A study of Rattus norvegicus with 12 samples.

How the data were processed

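Lung tissue with bronchi from 12 rats, labelled as male Sprague Dawley rats aged 8 weeks at 300 g, was sequenced on an Illumina instrument from Trizol-extracted RNA, 6 libraries per group. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 to the rat build mRatBN7.2 and counted with HTSeq 2.0.2; strand setting, filters and annotation release are not stated. The deposited table holds, for each library, raw read counts per Ensembl gene. It also holds FPKM values that the authors derived from the counts, and each FPKM equals the count scaled by gene length and by the library's total, to a relative deviation of at most 7e-14. The table has 23096 genes, of which 3108 carry no name, 187 names stand on more than 1 line and 3834 genes have 0 counts in all libraries. The genomic positions of the genes were not used. Totals ranged from 13723207 to 16271842 counts per library, with 16579 to 17354 genes detected. A count of 0 allows up to 3 counts, between 0.184 and 0.219 CPM by library, which covers counting error only.

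Groups followed the labels, and each library was counted as a separate rat. Counts were analysed with R 4.3.3 and edgeR 4.0.16: genes were kept by filterByExpr (14517 genes), scaled by TMM and tested by the quasi-likelihood F test (glmQLFit, glmQLFTest) with group as the only term, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The biological coefficient of variation was 31.1%. CPM values are TMM-scaled except where raw library totals are named. The 36 gene lists, with 762 entries (716 matched by symbol, 1 by synonym, 45 unmatched), were tested where at least 5 members passed the filter. They were tested by camera (limma 3.58.1) with a preset correlation of 0.01 and, beside it, with an estimated correlation, and by fry, with adjustment over the lists. By fry, which compares a list with no other genes, the matrix (adjusted p = 0.0174), smooth muscle (0.0174), mast cell (0.00185), secretory (0.0403), P450 (0.0264), cardiac (0.0264) and mitochondrial lists (0.0187) moved in one direction. List scores were means of log2 CPM with a prior count of 2, each gene centred over the 12 libraries, compared by exact two-sided permutation over 924 assignments (smallest p 0.00216). These 36 lists and their tests, the rule for named genes and the alternatives given below as chosen beforehand were fixed before the data were examined.

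Named genes were the 10 highest and 10 lowest fold changes among called genes with a mean FPKM of at least 1 in the higher group, a usable symbol and all 6 DA libraries on one side of the control mean. To these were added the 2 called members of each list with the smallest adjusted p (or the 2 most abundant where none was called) and 22 genes fixed by name. Of the 94 genes so named and tested, 75 were called, and 52 of these were called without each single library as well. Foxj1, Krt14 and Dcxr had no entry of that name and were not analysed here, and Muc5ac, Krt5 and Il6 were below the count filter. The table carries no annotation terms, so the planned test of terms was not run.

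On simulated counts of the same size and spread, with genes drawn independently, edgeR recovered 20.9% of 67 genes changed 1.5-fold. It recovered 70.2% of 67 changed 2-fold and 84.9% of 66 changed 4-fold. Of 14233 unchanged genes 7 were called, 5.645% of all calls there. Far fewer genes were changed than the 2316 called in the data, so these rates need not hold for the data. On simulated lists of independent genes, camera called 6 of 6 shifted and 0 of 30 unshifted lists.

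Alternatives chosen beforehand were limma on log2(FPKM + 0.5) and with offsets of 0.1 and 1, DESeq2 1.42.0, upper quartile scaling, no filter, a mean FPKM of at least 1, voom with quality weights, a replicate block, leaving out each library, an estimated correlation and a Pearson distance. Chosen after the data were seen were a term for Y-linked reads, a term for clock score, the libraries with or without Y-linked reads alone, and removal of the gene length trend, as well as the lists of sterol synthesis and glucocorticoid-induced genes. Of the 75 calls of named genes, 73 remained by DESeq2, 60 in limma at each offset (of 67 tested), 70 under voom with quality weights, 74 under upper quartile scaling, 72 with no filter and 65 with the clock term. With a mean FPKM of at least 1, 68 remained (of 68 tested), and with a replicate block 59.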

Results

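Lungs with their bronchi were profiled by RNA sequencing in 12 Sprague Dawley rats, 6 given water through the trachea (control) and 6 given 2,3-butanedione (diacetyl, DA). DA is a butter flavouring compound whose vapour is linked to bronchiolitis obliterans, the scarring closure of small airways. The dose was 125 mg/kg daily over 7 days, and tissue was taken 24 h after the last dose. The comparison addressed which genes and cell-type programmes differed between the DA and control lungs.

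Of 14517 genes tested, 1226 were higher and 1090 were lower in DA at an adjusted p under 0.05 in edgeR's quasi-likelihood test. At a fold of 2 or more the counts were 476 and 220. Values of the groups did not overlap in 877 genes, 6.04% of those tested, against 0.216% by chance. Whole profiles were farther apart between groups than within them, with a difference in mean distance (1 minus Spearman's correlation) of 0.0179. The exact one-sided permutation p was 0.00216, the smallest that the 924 assignments of the libraries give. The number of genes higher in DA varied with the library left out. It was 804, 595, 572, 732 and 655 without control replicate 2, 3, 4, 5 or 6, and 605 without DA replicate 1. Without DA replicate 2, 4 or 5 it was 1660, 1311 and 1325. In the fits with 804 or fewer, all 2316 called genes kept their sign, at a median ratio of fold changes of 0.968 to 1.01. The remaining libraries had served to pick these genes, so this is no independent check. Their median standard error went from 0.164 to between 0.172 and 0.177. The number lower in DA was 607, 579, 691 and 696 without control replicate 3, 4, 5 or 6, and 583 without DA replicate 1. At a fold of 2 or more, genes higher numbered 281, 269, 289 and 262 without control replicate 3, 4 or 6 or DA replicate 1, and genes lower numbered 142 without control replicate 4.

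Connective tissue genes rose. Of 31 tested fibrillar collagen and matrix protein genes, 18 rose and 0 fell, and 20 rose when adjusted over the list alone, with a median log2 fold change of 0.98. Col1a1 (ENSRNOG00000003897) rose by 1.95 ± 0.27 (SE) on the log2 scale (adjusted p = 0.00292), from 348 ± 71.9 CPM (read counts scaled by library size, SD, n = 6) to 1346 ± 542. The collagen cross-linking enzyme gene Loxl2 (ENSRNOG00000016758) rose by 1.78 (adjusted p = 0.00297), from 29.0 to 100.02 CPM on average. Lum, Cemip and Fndc1, which encode a collagen-binding proteoglycan, a hyaluronan-degrading protein and a fibronectin-domain protein, were among the 10 genes highest by the naming rule, at log2 fold changes of 3.23, 3.50 and 3.30. Cemip (ENSRNOG00000012442) went from 3.26 ± 2.03 to 37.0 ± 19.3 CPM (adjusted p = 0.00292). Col3a1 rose by 1.23 (adjusted p = 0.0215), a call that was lost without control replicate 4 (adjusted p = 0.0511). Fn1, at -0.09, was not called (adjusted p = 0.841). As a set the matrix genes rose by camera with a preset correlation between genes (adjusted p = 2.38e-12), while the adjusted p was 0.413 with an estimated correlation. The score of the list, its mean log2 level, was 1.00 higher in DA, with 6 of 6 DA libraries above the control mean (exact permutation test, adjusted p = 0.0195).

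Contractile genes of smooth muscle and myofibroblasts rose alongside. Of 13 tested, 8 rose and 0 fell, 8 of them also adjusted over the list alone, with a median log2 fold change of 1.53. Acta2 (ENSRNOG00000058039), which encodes smooth muscle actin, rose by 1.81 ± 0.27 (adjusted p = 0.00311), from 179 ± 41.8 to 625 ± 248 CPM (SD, n = 6). Cnn1 (ENSRNOG00000027736) rose by 2.47 ± 0.31 (adjusted p = 0.0029), from 30.9 ± 9.51 to 171 ± 74.0 CPM, and Myl9 rose by 1.60 (adjusted p = 0.00287). The list rose by camera (adjusted p = 2.64e-12, or adjusted p = 0.413 with an estimated correlation), and its score was higher in 6 of 6 DA libraries (difference 1.20; exact permutation test, adjusted p = 0.0195). Fibrosis regulators were divided. Of 23 tested genes of the TGF-beta pathway, 4 rose and 2 fell (4 and 3 adjusted over the list alone). The co-receptor gene Tgfbr3 fell by 1.53 (adjusted p = 0.00364). The log2 fold change of Tgfb1 itself, -0.25, was not called (adjusted p = 0.063), and was called lower without control replicate 3 (adjusted p = 0.0477) or DA replicate 5 (adjusted p = 0.0493), by DESeq2 (adjusted p = 0.0217) and with the gene length trend removed (adjusted p = 0.0252). Camera did not call the list (median 0.03, adjusted p = 0.779, or 0.954 with an estimated correlation).

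**Figure D1:**
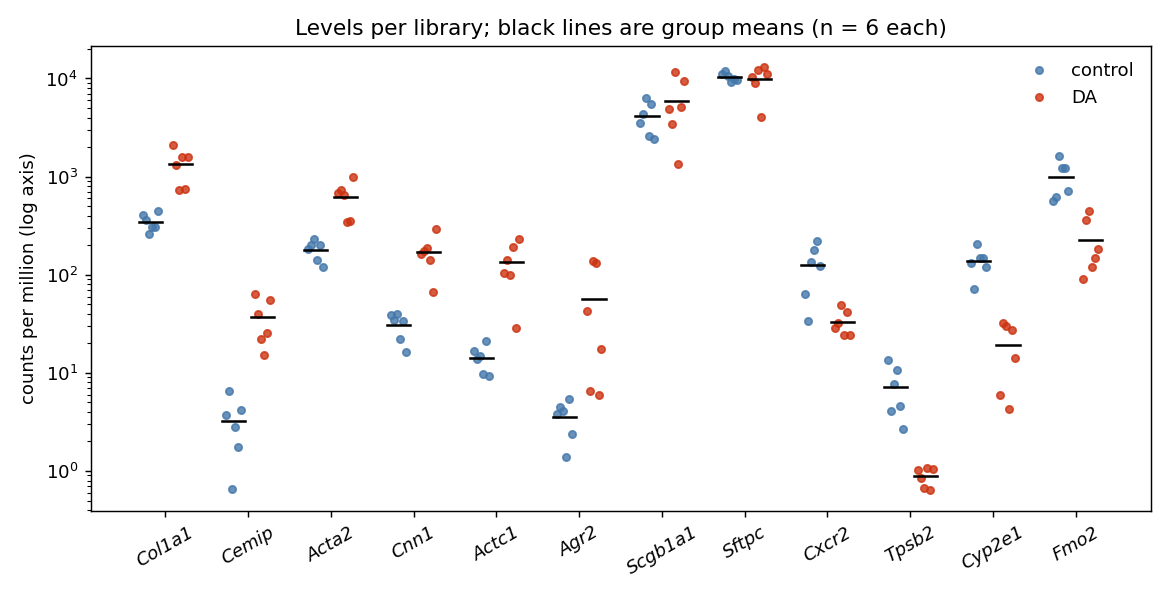
CPM (scaled read counts, log axis) of 12 genes in each library of control and DA, with points for libraries and a line for the group mean. Col1a1, Acta2 and Cnn1 lay higher in all 6 DA libraries than in any control, Cyp2e1, Fmo2 and Tpsb2 lay lower, and Scgb1a1 and Sftpc overlapped between the groups.

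Genes of airway secretory cells differed in part, unevenly between rats. Of 21 tested genes of club and other secretory cells, 8 rose and 1 fell (12 and 1 adjusted over the list alone), with a median log2 fold change of 1.16. Agr2 (ENSRNOG00000005023), needed for mucin folding, rose by 3.98 ± 0.80 (adjusted p = 0.00927), from 3.58 ± 1.45 to 56.6 ± 61.1 CPM (SD, n = 6). It was not called within the libraries without Y-linked reads alone, where the log2 fold change of Agr2 was 1.81 (adjusted p = 0.0808), nor within those with such reads (adjusted p = 0.503). The gene of the airway mucin Muc5b rose by 4.94 ± 1.25 (adjusted p = 0.0224), from 19.6 ± 14.7 to 599 ± 812 CPM. Only 4 of 6 DA libraries lay above its control mean, and the call was lost without control replicate 4 (adjusted p = 0.0513), in limma on log2(FPKM + 0.5), (FPKM + 0.1) and (FPKM + 1) (adjusted p = 0.111, 0.119 and 0.112) and under voom with quality weights (adjusted p = 0.0686). It was also lost with Y-linked reads as a term (adjusted p = 0.265), within the libraries with such reads (adjusted p = 0.503) and within those without, where the log2 fold change of Muc5b was 0.59 (adjusted p = 0.718). The club cell secretory protein gene Scgb1a1 was not called (log2 fold change 0.53, adjusted p = 0.416), at 4124 ± 1588 CPM in control and 5960 ± 3824 in DA. Muc5ac stayed below the count filter, with 3885 counts in DA replicate 4, 210 in DA replicate 1, 84 in DA replicate 3 and at most 27 in each other library. The secretory list rose by camera (adjusted p = 1.78e-04, or adjusted p = 0.475 with an estimated correlation). Its score lay above the control mean in 6 of 6 DA libraries but did not pass the exact permutation test (difference 1.41, adjusted p = 0.0779).

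Ciliated cell and axonemal genes had a median log2 fold change of 1.12. Of 30 tested, 6 rose and 0 fell, and 14 rose when adjusted over the list alone. Ccno (ENSRNOG00000010454), which drives the formation of many cilia per cell, rose by 4.53 ± 0.75 (adjusted p = 0.00445), from 1.27 ± 0.595 to 29.6 ± 34.2 CPM (SD, n = 6). Tekt2, a tubulin-associated gene of cilia, rose by 1.66 (adjusted p = 0.0055). The list rose by camera (adjusted p = 1.46e-07, or adjusted p = 0.634 with an estimated correlation), and its score difference of 0.95 did not pass the exact permutation test (adjusted p = 0.12). It was not called within the libraries without Y-linked reads alone (adjusted p = 0.447). The basal and squamous keratin list, of which 2 of 12 genes rose and 0 fell (3 and 1 adjusted over the list alone), was not called (median 0.33, adjusted p = 0.179, or 0.541 with an estimated correlation). It was called higher with no filter (adjusted p = 0.0271) and within the libraries without Y-linked reads alone (adjusted p = 0.0357). Krt15 rose by 0.73 (adjusted p = 0.00879). Krt5 was almost confined to DA replicate 4, with 839 counts there and at most 2 in each other library. The highest log2 fold change of a named gene, 5.40 ± 0.95 (adjusted p = 0.00556), was that of Gabrp (ENSRNOG00000032417), a GABA receptor subunit gene, from 0.868 ± 0.974 to 36.6 ± 41.6 CPM.

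Cell cycle genes were higher in the DA lungs, unevenly between rats. Of 28 tested, 19 rose and 0 fell, and 26 rose when adjusted over the list alone, with a median log2 fold change of 1.60. The replication gene Mcm5 rose by 1.68 (adjusted p = 0.0181) and the mitotic kinase gene Cdk1 by 2.23 (adjusted p = 0.0183). With Y-linked reads as a term neither the log2 fold change of Mcm5 (adjusted p = 0.0603) nor the log2 fold change of Cdk1 (adjusted p = 0.0604) was called. Nor was either called within the libraries without such reads (adjusted p = 0.161 and 0.153) or with them (adjusted p = 0.503 for both). The list rose by camera (adjusted p = 4.52e-11, or adjusted p = 0.498 with an estimated correlation), and its score lay above the control mean in 6 of 6 DA libraries without passing the exact permutation test (difference 1.27, adjusted p = 0.0668). The scores of DA replicates 2, 3 and 5, at -0.17, 0.03 and -0.24, lay near those of control replicates 4 to 6 (-0.11, -0.19 and -0.29). DA replicates 1, 4 and 6 stood higher, at 1.44, 2.01 and 0.75, and control replicates 1 to 3 lower, at -0.82, -1.09 and -1.31.

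Mast cell and eosinophil genes were lower. Of 13 tested mast cell and eosinophil genes, 8 fell and 0 rose (10 and 1 adjusted over the list alone), with a median log2 fold change of -1.55. The mast cell tryptase gene Tpsb2 (ENSRNOG00000018611) fell by 3.02 ± 0.40 (adjusted p = 0.00292), from 7.22 ± 4.26 to 0.886 ± 0.197 CPM (SD, n = 6), the lowest fold change of a named gene. The IgE receptor gene Ms4a2 fell by 1.88 (adjusted p = 0.00445). The list fell by camera (adjusted p = 1.00e-06, or adjusted p = 0.137 with an estimated correlation), and its score was lower in 6 of 6 DA libraries (difference -1.20; exact permutation test, adjusted p = 0.0195).

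Of 14 tested neutrophil genes, 6 fell and 0 rose (7 and 1 adjusted over the list alone), with a median log2 fold change of -0.98. The chemokine receptor gene Cxcr2 fell by 1.92 ± 0.38 (adjusted p = 0.00883), from 126 ± 69.9 to 33.3 ± 9.94 CPM (SD, n = 6), and Selplg fell by 0.95 (adjusted p = 0.0062). The list fell by camera (adjusted p = 0.0041, or adjusted p = 0.634 with an estimated correlation) and was not called with Y-linked reads as a term (adjusted p = 0.0743), under voom with quality weights (adjusted p = 0.0563) or within the libraries with Y-linked reads alone, where its direction was upward (adjusted p = 0.415). Its score was -0.24 and -1.04 in control replicates 1 and 2, against a DA mean of -0.31, so the fall rested on control replicates 3 to 6. Alveolar macrophage genes, with 3 of 10 lower and 0 higher (5 and 0 adjusted over the list alone), had a median of -0.49 (camera adjusted p = 0.00622, or adjusted p = 0.498 with an estimated correlation), and were not called within the libraries without Y-linked reads alone (adjusted p = 0.122). Siglec5 among them fell by 1.45 (adjusted p = 0.0125). T cell and NK cell genes, with 5 of 22 lower and 0 higher, had a median of -0.47 (camera adjusted p = 2.05e-04, or adjusted p = 0.56 with an estimated correlation), and the perforin gene Prf1 fell by 1.25 (adjusted p = 0.0134). The T cell and NK cell score of DA replicate 4 was 0.61, above the control mean of 0.33, against -0.86 to -0.10 in the other DA libraries. Monocyte and recruited macrophage genes, with 3 of 21 lower and 0 higher, had a median of -0.24 (camera adjusted p = 0.0415, or adjusted p = 0.84 with an estimated correlation). That call was lost without control replicate 4, 5 or 6 (adjusted p = 0.0795, 0.115 and 0.272) and without DA replicate 2, 3 or 5 (adjusted p = 0.156, 0.108 and 0.0524). It was also lost in limma on log2(FPKM + 0.5), (FPKM + 0.1) and (FPKM + 1) (adjusted p = 0.0728, 0.0749 and 0.0712), with a mean FPKM of at least 1 (adjusted p = 0.056) and under voom with quality weights (adjusted p = 0.0569). The same held with Y-linked reads as a term (adjusted p = 0.225), with the clock score as a term (adjusted p = 0.334) and within the libraries with Y-linked reads alone (upward, adjusted p = 0.711). Apoe among them fell by 1.72 (adjusted p = 0.015), from 806 to 245 CPM. Thymocyte genes, with 2 of 6 lower, had a median of -0.73 (camera adjusted p = 0.024, or adjusted p = 0.498 with an estimated correlation), a call lost without DA replicate 2 (adjusted p = 0.0732) or DA replicate 3 (adjusted p = 0.0542), under DESeq2 (adjusted p = 0.0554) and with no filter (adjusted p = 0.154). DA replicate 4 had the highest thymocyte score of the 12 libraries, 0.84.

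Inflammatory mediators did not move together. Of 31 tested cytokine and chemokine genes, 3 rose and 1 fell, and the list was not called (median 0.28, camera adjusted p = 0.308, or 0.84 with an estimated correlation). The monocyte chemokine gene Ccl2 rose by 2.27 (adjusted p = 0.0175), from 3.01 to 14.5 CPM, and Ccl5 fell by 1.44 (adjusted p = 0.00606), from 95.8 to 35.3 CPM. Il1b (-0.79, adjusted p = 0.308), Tnf (0.53, adjusted p = 0.483) and Cxcl1 (0.79, adjusted p = 0.12) were not called, and Il6 stayed below the count filter, at 33, 38 and 26 counts in DA replicates 1, 4 and 6, at most 5 in the other DA libraries and 2 to 10 in the controls. Il1b was called lower without DA replicate 4, at a log2 fold change of -1.39, and under voom with quality weights, where the log2 fold change of Il1b was -1.42 (adjusted p = 0.0308). Of 23 interferon-stimulated genes, 0 rose and 2 fell (1 adjusted over the list alone). Ifit1 fell by 2.98 (adjusted p = 0.0091), from 53.1 to 6.71 CPM, while the list was not called (median -0.21, camera adjusted p = 0.0875, or 0.888 with an estimated correlation). It was called lower without control replicate 3, 4 or 5 (adjusted p = 0.0181, 0.0186 and 0.0241) and without DA replicate 1 or 5 (adjusted p = 0.0447 and 0.00252), and also under upper quartile scaling (adjusted p = 0.046) and within the libraries with Y-linked reads alone (adjusted p = 7.70e-07). MHC class II genes were not called as a list (0 higher and 1 lower of 17, median -0.19, adjusted p = 0.164, or 0.888 with an estimated correlation), but were called lower without control replicate 3 (adjusted p = 0.0319) or DA replicate 4 (adjusted p = 0.0133) and within the libraries without Y-linked reads alone (adjusted p = 0.0468). Of 16 B cell and plasma cell genes, 0 rose and 0 fell by edgeR. Their median (0.47) and mean (0.67) were above 0, while camera's direction and the score difference (-0.12) were below it (adjusted p = 0.992, or 0.995 with an estimated correlation). DA replicate 4 had a B cell score of 2.57, against 0.07 at most in the other DA libraries, and without it the list was called lower (adjusted p = 0.00203).

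Some genes of xenobiotic metabolism were lower. Of 18 tested cytochrome P450 and flavin monooxygenase genes, 7 fell and 0 rose, the same counts as adjusted over the list alone, with a median log2 fold change of -0.56. Cyp2e1 (ENSRNOG00000012458) fell by 2.84 ± 0.47 (adjusted p = 0.00445), from 137 ± 43.2 to 19.1 ± 12.6 CPM (SD, n = 6). Fmo2 (ENSRNOG00000003510) fell by 2.15 ± 0.42 (adjusted p = 0.00804), from 996 ± 430 to 225 ± 144 CPM. The list fell by camera (adjusted p = 7.49e-05, or adjusted p = 0.42 with an estimated correlation), with a score difference of -0.82 that did not pass the exact permutation test (adjusted p = 0.0649). The methyltransferase gene Inmt fell by 2.72 (adjusted p = 0.00525), from 82.3 to 12.5 CPM.

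Genes of carbonyl and oxidative stress responses moved in both directions, and their lists were not called by camera. By fry in either direction, the NRF2 and glutathione list (adjusted p = 0.000791), the hypoxia and glycolysis list (adjusted p = 0.000791) and the dicarbonyl and aldehyde list (adjusted p = 0.00442) were called. Of the other lists that camera did not call, fry in either direction called the TGF-beta (adjusted p = 1.14e-07), alveolar type 2 (adjusted p = 0.00205), basal keratin (adjusted p = 0.00442), cytokine (adjusted p = 0.00472) and metalloproteinase lists (adjusted p = 0.0235). Of 33 NRF2 and glutathione genes, 3 rose and 2 fell, with a median of -0.04, a mean of 0.04 and an upward camera direction that was not called, against a score difference of -0.0022 (adjusted p = 0.992, or 0.995 with an estimated correlation). Gpx2 rose by 1.08 (adjusted p = 0.0057) and Prdx1 by 0.69 (adjusted p = 0.0057). Nqo1 (0.34, adjusted p = 0.342) and Hmox1 (-0.14, adjusted p = 0.809) were not called. Of 21 dicarbonyl and aldehyde metabolism genes, 2 rose and 1 fell (1 and 1 adjusted over the list alone, median 0.10, camera adjusted p = 0.598, or 0.888 with an estimated correlation), and the reductase gene Akr1a1 rose by 0.46 (adjusted p = 0.0187). The unfolded protein response list (0 higher and 1 lower of 22, median -0.06, adjusted p = 0.64, or 0.954 with an estimated correlation) was not called. Neither, by camera, was the hypoxia and glycolysis list (1 higher and 2 lower of 19, median 0.06, adjusted p = 0.992, or 0.995 with an estimated correlation), whose score difference was -0.02. Ddit3 fell by 0.62 (adjusted p = 0.015). The immediate early genes (0 higher and 0 lower of 19 by edgeR, median 0.20, adjusted p = 0.657, or 0.954 with an estimated correlation) were not called either.

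Few alveolar genes were called, while some endothelial genes were lower. Of 18 alveolar type 2 cell genes, 1 rose and 0 fell, with a median of -0.02, a mean of 0.09 and a downward camera direction that was not called (adjusted p = 0.839, or 0.995 with an estimated correlation). The gene that rose, the chitinase gene Chia, did so by 2.01 (adjusted p = 0.00364), from 201 to 813 CPM. The surfactant gene Sftpc, at -0.06, was not called (adjusted p = 0.891). Of 16 alveolar type 1 cell genes, 0 rose and 0 fell by edgeR (median 0.42, camera adjusted p = 0.548, or 0.954 with an estimated correlation), and without DA replicate 4 the list was called higher (adjusted p = 0.00138), as it was under voom with quality weights (adjusted p = 0.0343) and within the libraries without Y-linked reads alone (adjusted p = 3.47e-09). Of 19 endothelial genes, 4 fell and 0 rose (7 and 1 adjusted over the list alone, median -0.47, camera adjusted p = 0.00134, or adjusted p = 0.674 with an estimated correlation). Without DA replicate 4 the endothelial list was no longer called (adjusted p = 0.0648). The vascular phosphatase gene Ptprb fell by 1.19 (adjusted p = 0.0213), from 1480 to 648 CPM, a call lost without DA replicate 1 (adjusted p = 0.051).

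Proteinase, mesothelial and rarer lists were not called across all 12 libraries. The matrix metalloproteinase and inhibitor list (1 higher and 1 lower of 13; 1 and 2 adjusted over the list alone) had a median of 0.15, a mean of -0.02 and an upward camera direction (adjusted p = 0.657, or 0.915 with an estimated correlation), and was called higher within the libraries with Y-linked reads alone (adjusted p = 0.0122). Mmp9 fell by 1.98 (adjusted p = 0.0363), a call lost without control replicate 3, 4, 5 or 6 or DA replicate 1, 3, 5 or 6 (adjusted p up to 0.0822). The call for the log2 fold change of Mmp9 was also lost in limma on log2(FPKM + 0.5), (FPKM + 0.1) and (FPKM + 1) (adjusted p = 0.102, 0.104 and 0.102), and under voom with quality weights (adjusted p = 0.121). The same held with terms for Y-linked reads (adjusted p = 0.315) or clock score (adjusted p = 0.0917) and within the libraries with Y-linked reads (0.50, adjusted p = 0.705). Mmp12 (1.44, adjusted p = 0.132) and Timp1 (0.54, adjusted p = 0.284) were not called. The mesothelial (2 higher and 0 lower of 9, median 0.30, adjusted p = 0.286, or 0.862 with an estimated correlation) and neuroendocrine lists (1 higher and 0 lower of 5, 1 and 1 adjusted over the list alone, median 0.32, adjusted p = 0.857, or 0.954 with an estimated correlation) were not called. The mesothelial list was called lower within the libraries with Y-linked reads alone (adjusted p = 0.0359) and higher within those without (adjusted p = 1.41e-08). Within the libraries with Y-linked reads the erythroid list was called higher (adjusted p = 0.00854). The erythroid list (1 higher and 0 lower of 9, median 0.40, adjusted p = 0.64, or 0.954 with an estimated correlation) and the cartilage list (0 higher and 1 lower of 5, median -0.15, adjusted p = 0.582, or 0.84 with an estimated correlation) were not called. The adipocyte list (0 higher and 0 lower of 6 by edgeR, median -0.77, adjusted p = 0.0875, or 0.639 with an estimated correlation) was called lower without control replicate 2 (adjusted p = 0.0487) or DA replicate 4 (adjusted p = 0.0295) and within the libraries without Y-linked reads alone (adjusted p = 0.015).

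Of the 20 members of the cardiac and skeletal muscle list, 6 were tested. Among these 6, 4 rose and 0 fell (5 and 0 adjusted over the list alone), with a median log2 fold change of 2.85. Actc1 (ENSRNOG00000008536), which encodes cardiac actin, rose by 3.22 ± 0.41 (adjusted p = 0.0029), from 14.3 to 133 CPM, and Ryr2 rose by 2.47 (adjusted p = 0.0106). In DA replicates 1, 2 and 6 Actc1 stood at 105, 140 and 219 CPM (by raw library totals). The heart muscle genes Myh6 and Myl7 were at most at 0.07 CPM there, so Actc1 rose in these libraries without them. Tnnt2, at 4.24 (adjusted p = 0.0278), rested on DA replicate 4, without which the log2 fold change was 1.47, and its call was lost without control replicate 2, 3, 4, 5 or 6 (adjusted p up to 0.0616). The list rose by camera (adjusted p = 0.00246, or adjusted p = 0.42 with an estimated correlation), with a score 1.70 higher and 6 of 6 DA libraries above the control mean (exact permutation test, adjusted p = 0.0195). Mitochondrially encoded genes rose as well, 8 of 12 with 0 lower (11 and 0 adjusted over the list alone, median 0.62, camera adjusted p = 4.03e-08, or adjusted p = 0.42 with an estimated correlation). Their score was 0.63 higher (exact permutation test, adjusted p = 0.0312), and Mt-co2 rose by 0.87 (adjusted p = 0.0105). Ribosomal protein genes, with 1 of 21 higher and 0 lower (0 and 0 adjusted over the list alone), had a median of 0.22 (camera adjusted p = 0.00622, or adjusted p = 0.84 with an estimated correlation). The ribosomal call was lost without DA replicate 4 (adjusted p = 0.057) and within the libraries with Y-linked reads alone (adjusted p = 0.27).

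**Figure D2:**
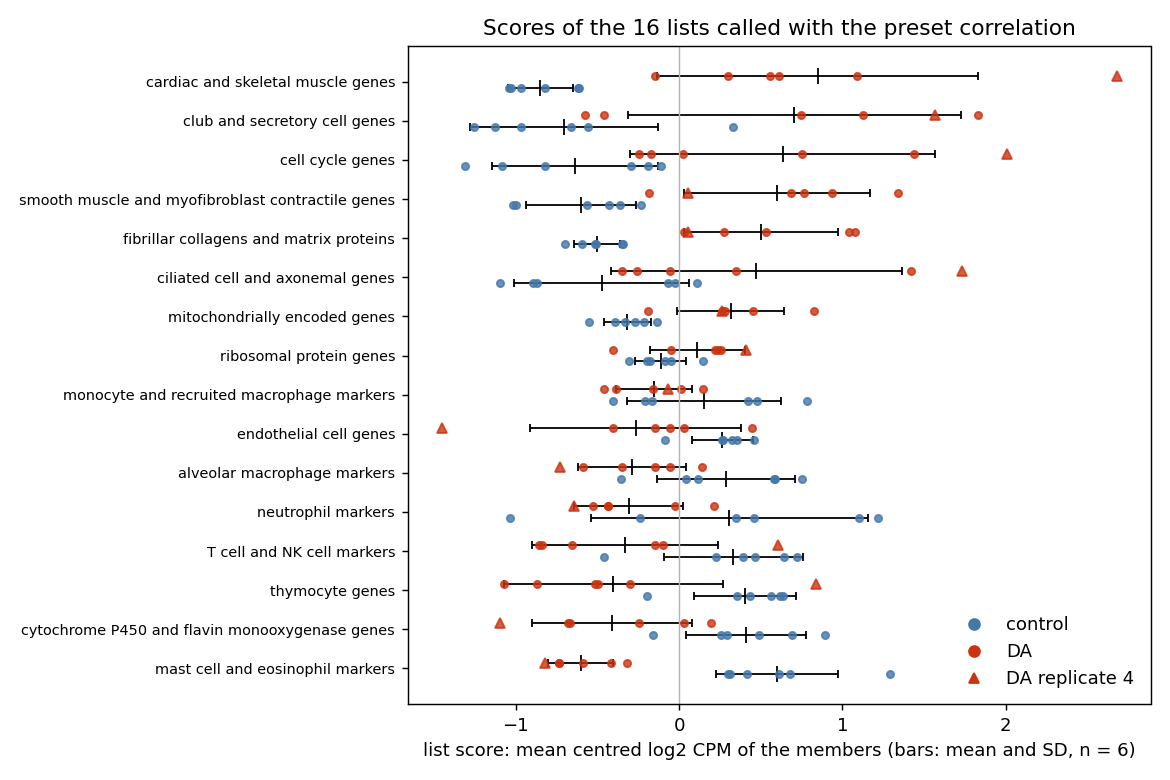
Scores (mean log2 level over a list's genes, each centred on its mean over the 12 libraries) of the 16 lists called by camera with a preset correlation, per library, with group mean and SD, and with DA replicate 4 drawn as a triangle. The matrix and smooth muscle scores of all 6 DA libraries lay above those of all controls, while ciliated scores overlapped, with 3 DA libraries above all controls.

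Members of lists behind counts of 5 or fewer, chosen after their values were seen where the naming rule had not picked them, included the following. In the TGF-beta list Tgfb3, Ltbp2 and Grem1 rose and Smad4 fell. Mrc1 and Lpl fell among alveolar macrophage genes, Csf1r and Cd163 among monocyte genes, and Nkg7, Gzmk, Klrd1 and Klrk1 among T cell and NK cell genes. Ccl12 and Ccl19 rose, and Oasl, Clec9a and the secretory list's Cyp4b1 fell. Flt1, Tek and Ednrb fell among endothelial genes, and Cd1d1 and Ccr9 among thymocyte genes. Adamts8, Perp, Msln, Itln1, Ddc, Me1, Aldh7a1, Ldha, Bhlhe40, Epb42, Tnni3 and Rplp1 rose, and Osgin1, Sqstm1, Aldh3a2, Pfkfb3, Slc16a3, Per1 and Cytl1 fell. Grem1 had the highest log2 fold change of the TGF-beta list, 4.06 (adjusted p = 0.00502). Among these genes, Tgfb3, Grem1, Csf1r, Gzmk, Clec9a, Cd1d1 and Ccr9 kept their calls without each single library. The others lost theirs without at least 1 of control replicates 1 to 6 or DA replicates 1 to 6, with adjusted p up to 0.149 (Tnni3). Without DA replicate 4 the log2 fold change of Ccl19 was 1.28 instead of 3.88, and that of Tnni3 was 0.96 instead of 3.76.

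Where no count adjusted over the list alone is given, it equalled the count over all genes. In all, 8 lists were called higher and 8 lower with the preset correlation. With an estimated correlation camera called 0 of the 36, and the exact permutation test on scores called 5, those of matrix, smooth muscle, mast cell, cardiac muscle and mitochondrial genes. Regroupings of the libraries called list numbers as large, so the number of lists called could not be set apart from chance.

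Libraries also differed in Y-linked transcripts and in clock phase, chosen for report after their values were seen. All 12 rats are labelled male, yet Kdm5d, Eif2s3y and Uty had 0 counts in 6 libraries, control replicates 3 to 6 and DA replicates 5 and 6, which allows at most 3 counts for each gene and library. The other 6 libraries, control replicates 1 and 2 and DA replicates 1 to 4, held 29.3 to 82.4 CPM of each (by raw library totals). With Y-linked reads as a term, 549 genes were higher and 572 lower in DA, of which 1089 were called in the same direction without the term. Within the 6 libraries without Y-linked reads, 4 control and 2 DA, 710 genes were higher and 979 lower. Of 75 calls of named genes, 51 remained with the term and 50 within the libraries without such reads. Calls lost included those of Agr2, Siglec5, Gzmk, Ccl2, Gpx2, Ryr2 and Ccr9 in the libraries without such reads, which leaving out any single library had not ended. Within the 6 with such reads, 2 control and 4 DA, edgeR called 0 genes (1388 at an unadjusted p under 0.05, and 304 by DESeq2). There 2303 of the 2316 called genes, which these libraries had helped to pick, kept their sign. A test of whether the DA effect differed by Y-linked reads called 0 genes by edgeR (1137 at an unadjusted p under 0.05; smallest adjusted p = 0.0774). It rested on only 2 or 4 libraries in each combination of group and Y-linked reads, so it cannot show that the effect was the same. Among clock genes, 1 of 17 rose and 1 fell (median -0.24, camera adjusted p = 0.64, or 0.888 with an estimated correlation; called lower within the libraries with Y-linked reads, adjusted p = 1.05e-04), and the score difference was above 0, at 0.02, where median and test were below it. The clock output gene Dbp ranged from 8.42 to 265 CPM in the control libraries and from 29.3 to 85.9 CPM in the DA libraries.

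**Figure D3:**
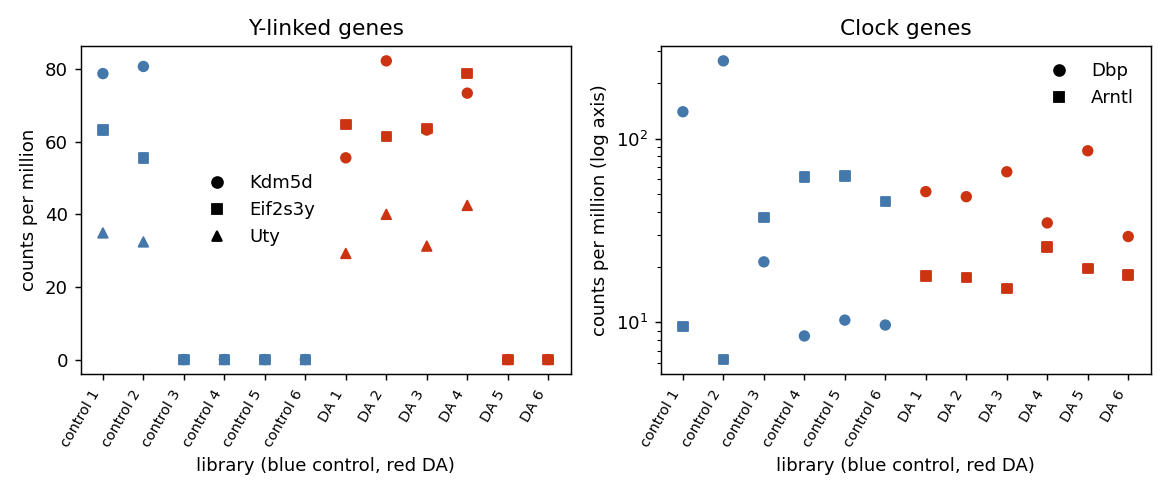
Left, CPM (by raw library totals) of Kdm5d, Eif2s3y and Uty in each of the 12 libraries; right, CPM (log axis) of Dbp and Arntl in the same libraries, each point a library. The Y-linked genes were at 0 in 6 libraries, 4 control and 2 DA, and Dbp was at 140 and 265 CPM in control replicates 1 and 2.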

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

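The tests of other groupings of the libraries were set beforehand, and the tests of Y-linked reads, clock phase, gene length, heart muscle and airway wall were chosen only after the result was seen. In 266 groups of 6 values (each named gene, each list score, total counts, clock score and mitochondrial percentage, in each group of rats), the highest or lowest library was compared with the others by Dixon's gap criterion, which chance passes in about 1 in 20 groups. It was passed in 24 groups, 9.02%, and 9 of these concerned DA replicate 4. In that library log2 CPM was 5.07 for Chst5 (0.41 to 1.51 in the other DA libraries), 6.29 for Tnnt2 (0.29 to 2.32), 3.78 for Ccl5 (4.996 to 5.59), 8.94 for Clic5 (10.46 to 11.13), 8.85 for Cav1 (10.02 to 10.62), 4.599 for Lipe (5.86 to 6.36) and 11.98 for Sftpc (13.13 to 13.67). Its scores were 2.57 for the B cell list (-0.92 to 0.07 in the others) and -1.27 for the alveolar type 1 list (0.18 to 0.53). Elsewhere in DA, C5 was at 1.30 (3.86 to 4.99) and Clec4d at 0.63 (2.09 to 2.88) in DA replicate 6, and Cd1d1 was at 4.42 (4.05 to 4.19) in DA replicate 3.

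Among controls, replicate 6 stood apart for Csf1r at 8.70 (8.33 to 8.46 in the other controls), Oasl at 5.39 (3.86 to 4.13), Gpx2 at 5.43 (6.22 to 6.52), Cfd at 5.70 (3.67 to 4.31), the endothelial score at -0.0855 (0.26 to 0.46) and the adipocyte score at 1.66 (-0.21 to 0.30). Control replicate 3 did so for Tgfbr3 at 8.85 (7.76 to 8.10), Tgfb1 at 6.63 (6.86 to 6.99) and the thymocyte score at -0.20 (0.35 to 0.64). Control replicate 2 did so for Il1b at 4.71 (6.20 to 6.93) and the alveolar type 2 score at 0.23 (-0.12 to -0.05), and control replicate 4 for Chst5 at -2.88 (-1.25 to -0.42).

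The genes called between DA and control were set against chance and against library structure. Of 100 splits drawn from 462, only 1, the real split, gave as many genes (1226 higher and 1090 lower against at most 399, and 476 and 220 at 2-fold against at most 111). Chance alone is therefore an unlikely source of these gene numbers, as far as the 100 splits drawn can tell. For list numbers it cannot be set aside: 72 of 100 called at least 8 lists in either direction (up to 17), where the real split called 8 higher and 8 lower. Fold changes of the 2316 called genes shrank little with a term for Y-linked reads (median ratio 0.962) or clock score (0.98). The same held with the length trend removed (0.974), and all kept their sign. This argues against the length trend as the whole cause. For Y-linked reads and clock score the ratios cannot decide, because the genes were picked by their difference between the groups. A gene that followed either alone would vary within a group and could hardly be called. With the Y-linked term 1089 of the calls remained: the median size of the log2 fold change went from 0.68 to 0.65 and its median standard error from 0.16 to 0.17, over all called genes. Of the 1227 calls lost, 1101 had a larger standard error and 954 a smaller fold (medians from 0.64 to 0.58, with standard errors from 0.18 to 0.19). In 455 of them p stayed within the range called before, so these ended by the adjustment for all genes. The sex of the rats stays open as a contributor, because the Y-linked split is uneven between groups (2 of 6 control and 4 of 6 DA libraries with reads). So does the hour of sampling, because the clock score differed in spread between groups (SD 3.18 in control and 0.419 in DA). Among controls both splits coincide. Control replicates 1 and 2 had Y-linked reads and clock scores of 2.43 and 3.47, and control replicates 3 to 6 had no such reads and scores from -3.68 to -1.13. Sex and hour therefore cannot be told apart among the controls. With both terms in the fit, 695 genes were higher and 687 lower in DA.

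Heart muscle transcripts were high in DA replicate 4, at 249 CPM (by raw library totals) for Myh6 and 109 CPM for Myl7. DA replicate 3 held less of them, at 5.7 and 5.8 CPM, and control replicate 5 had 1.7 CPM of Myh6. For DA replicate 4 ventricular muscle is argued against, since the higher of its light chains Myl2 and Myl3, at 0.967 CPM, came to 0.388% of Myh6. A piece with less alveolar tissue may apply there: of the alveolar type 1 and endothelial scores of DA replicate 4, 2 of 2 (-1.27 and -1.45) lay below all other 11 libraries (lowest -0.38 and -0.40). Muscle of atrial type or from the walls of large lung veins was not tested, and no biological effect of DA can be tested on so few libraries. Actc1 kept its call without DA replicate 4.

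Smooth muscle and ciliated lists were both higher in DA, as a larger share of airway wall in the DA pieces could produce. Smooth muscle scores lay above all controls in 6 of 6 DA libraries, and in 3 DA libraries the smooth muscle score lay above all controls and the ciliated score did not. Because sampling follows the groups and a loss of ciliated cells would part the lists in the same way, a larger share of airway wall and a change within the airway cannot be told apart here. The effect of DA on airway tissue stays open as the biological explanation.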

How the results depend on the processing

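The settings with Y-linked reads, clock score or gene length were tests chosen only after the result was seen. The 2316 called genes kept their direction in each setting in which they were tested, save in the libraries with Y-linked reads alone, where 99.4% did. Every setting used libraries that had served to pick these genes, so a kept direction is no independent check. Counts moved as follows, and unless stated the cause was not tested. Limma on log2(FPKM + 0.5) called 185 genes higher and 144 lower at 2-fold or more, with 259 higher for an offset of 0.1, and 136 and 108 for an offset of 1. Folds were smaller as the offset grew (median ratio to edgeR 0.913, 0.972 and 0.851 in this order), but test, unit and genes tested (13676) differed as well, so the drop was not traced to the offset. DESeq2 called 1888 higher and 1645 lower, and voom with quality weights called 2034 and 1932. Upper quartile scaling called 1662 higher and 853 lower, 66.1% higher against 52.9% with TMM, as it moved the median log2 fold change of all genes from 0.03 to 0.08. List scores passed in 8 lists, not 5, under upper quartile scaling, no filter and a mean FPKM of at least 1.

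With a replicate block, 677 genes were higher and 757 lower, 289 and 183 at 2-fold, and 0 list scores passed a paired sign-flip test, whose few sign patterns limit p (adjusted p = 0.141 for matrix genes, and camera on the same fit called 8 lists higher and 8 lower). The labels give no shared animal, and residual profiles of the same number correlated at 0.11, 0.18, 0.30, 0.0393, -0.26 and 0.0032 for replicates 1 to 6. Controls 1 to 3 correlated best with their own number and controls 4 to 6 did not, a hint from the data only, so the numbers were not taken as pairs. Named genes whose calls ended with the block included Agr2, Muc5b and Mmp9. A term for Y-linked reads left 549 higher and 572 lower, 200 and 120 at 2-fold. Within libraries with such reads edgeR called 0, 0, 0 and 0 (1388 genes at an unadjusted p under 0.05, 304 by DESeq2). There Fpr1 and Mmp9 reversed, to 0.68 and 0.50, neither called. Within libraries without such reads, 6 as well, 710 were higher and 979 lower, and 278 and 399 passed 2-fold. With an estimated correlation camera called 0 lists higher and 0 lower (preset: 8 and 8, and 5 by exact score test).

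Leaving out 1 library gave 572 to 1660 genes higher, 579 to 1456 lower, 262 to 617 and 142 to 280 at 2-fold, 8 to 8 lists higher, 6 to 10 lower, and 5 to 11 list scores (11 without DA replicate 2, 8 without DA replicate 4). Genes higher were fewest without control replicate 4 (572), then control 3 (595), DA 1 (605), control 6 (655), control 5 (732) and control 2 (804), and genes lower without control 4 (579), DA 1 (583), control 3 (607), control 5 (691) and control 6 (696). Separation of the groups kept its p of 0.00216 in 3 other settings (0.0206, 0.0087 and 0.0214). The test of annotation terms was not run, nor were median-of-ratios and quantile scaling of FPKM, since counts were the main unit. Exact score tests under added terms, within Y-linked subsets and under voom weights gave no value. Depth limits genes near the floor of 3 counts, such as Il6 and Krt5.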

Other observations

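All tests of the sterol and glucocorticoid lists were chosen only after the result was seen, since some of their genes had been noticed among the called genes before the lists were made. Of 21 sterol synthesis genes, 14 rose and 0 fell in DA, with a median log2 fold change of 0.87. Hmgcs1 rose by 1.59 ± 0.20 (SE) on the log2 scale (edgeR, adjusted p = 0.00287) and Idi1 by 1.73 (adjusted p = 0.00292). The score was -0.40 ± 0.26 in control and 0.40 ± 0.25 in DA (SD, n = 6), a difference of 0.807 (exact permutation p = 0.00216, the smallest possible; camera p = 3.89e-16, and p = 0.023 with an estimated correlation). It was 0.75 with a clock term, 0.72 with a Y-linked term and 0.78 without DA replicate 4. A rise of sterol synthesis in the lung after DA may be one reading. These genes cannot test it, since some led to the list.

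Of 17 genes that glucocorticoids induce, 7 fell and 0 rose, with a median of -0.996. Klf15 fell by 1.59 (adjusted p = 0.00789) and Tsc22d3 by 1.10 (adjusted p = 0.0119), while Fkbp5 was not called (-1.22, adjusted p = 0.0614) and Lcn2 and Sgk1 were above 0 without a call (1.30 and 0.27). The score difference was -0.899 (exact permutation p = 0.026; camera p = 1.05e-05, and p = 0.128 with an estimated correlation), -0.66 with a clock term and -0.69 with a Y-linked term. It rested on control replicates 3 to 6, at 0.50 to 1.17, whereas control replicates 1 and 2, at -0.56 and -0.46, lay within the DA range. Among libraries with Y-linked reads it was 0.11, and among those without -1.48. Without DA replicate 4 it was -0.86 (exact permutation p = 0.0519). Lower glucocorticoid-driven transcription in DA may be one reading, but the genes were chosen after they were seen, so these values cannot tell. Hormone levels were not analysed here, and Zbtb16 and Per1, also named among the genes of the rule, are members.

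The Y-linked split had a counterpart in an unnamed gene, ENSRNOG00000037911, at 50.4 to 141 CPM in the 6 libraries without Y-linked reads and at most 1.78 CPM in the others (by raw library totals). Kdm6a was lower by 0.73 on the log2 scale in libraries with Y-linked reads (adjusted p = 0.00252). The term for Y-linked reads itself called 8 genes. These values argue against the male label for the 6 libraries without Y-linked reads. Whether animals or samples differ from their labels was not tested.

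Arntl was at 9.46 and 6.27 CPM in control replicates 1 and 2 and at 37.2 to 62.8 CPM in control replicates 3 to 6. The SD of the clock score was 3.18 in control and 0.419 in DA. Control replicates 4 and 5 had the most similar counts of all pairs of libraries. Their chi-square per degree of freedom was 8.85, against 24.67 for the next closest pair, control replicates 3 and 5. Spearman correlations between controls had a median of 0.9696 and a maximum of 0.9912. Whether control replicates 4 and 5 share an animal or a preparation was not tested. If they do, n = 6 overstates the control group. Mitochondrially encoded genes took 2.95 to 3.62% of counts in control and 3.50 to 6.64% in DA. Median log2 fold change ran from 0.13 in the shortest of 5 classes of gene length to -0.08 in the longest, with a Spearman correlation of -0.141 across genes, which are not independent replicates. The direction of calls followed length too, with 271 genes higher and 106 lower in the shortest class and 162 higher and 372 lower in the longest. With the length trend removed, 2016 of the 2316 calls remained.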
